A study of Homo sapiens with 8 samples.

How the data were processed

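RNA sequencing was performed on 8 libraries of the human uveal melanoma cell line MEL202, which carries a mutation in the splicing factor gene SF3B1. The labels give 4 lines, each with and without Shld: parental cells, a line with the mutant SF3B1 allele knocked out, a line with a destabilising domain on mutant SF3B1 (here the mutant degron line) and a line with that domain on wildtype SF3B1 (the wildtype degron line). Shld is a small ligand that stabilises the destabilising domain, so its withdrawal leads to degradation of the tagged protein. There were 8 groups with 1 library each, so no group had replicates. Per the labels' protocols, TruSeq libraries were sequenced on a HiSeq instrument with paired reads of 100 bases. Per the submitters' processing notes, TopHat, Cufflinks and the hg19 build were used. Their versions, the annotation and whether strand was used are not given in the sources used here.

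The authors deposited 1 table of 32087 loci with FPKM-type values (fragments scaled by transcript length and library size) from which each library had been rescaled. The 75th percentile over all loci was 10 in every column, from 9.99 to 10.00. That FPKM was the input of this rescaling is inferred from Cufflinks being named and from the values, and is not stated outright. Loci carry Cufflinks identifiers and gene names. No coordinates are given here, because the annotation used for transcript lengths is on another build than hg19. The values are not counts, so the absolute depth of each library is unknown. Low values between 0.001 and 0.3 were compared locus by locus with the parental library with Shld. They gave between 1.05 and 1.48 times as many fragments per unit of value in the other libraries. With and without Shld the factors were 1.45 and 1.05 in the knockout line and 1.48 and 1.05 in the mutant degron line. They were 1.19 and 1.07 in the wildtype degron line, and 1.09 in parental cells without Shld. Each library listed between 13430 and 14080 loci at 0. An exact 0 may be a failed estimate, so values at 0 are given as listed.

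Columns were matched to samples by their names. The column names of the knockout line describe cells with the mutant allele knocked out and, in addition, the destabilising domain knocked in at wildtype SF3B1, with 4 days without Shld. The sample labels name no degron for this line and give 2 days. For both degron lines the labels give 2 days, as do the column names of their libraries without Shld. The parental column without Shld is also named as 4 days, a time its label does not give. The planned model had taken the knockout line, like the parental cells, as a line without a degron whose pair of libraries measures only the spread. That assumption may be wrong, so its results are given as planned and a second model was added.

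The planned model used limma 3.58.1 in R 4.3.3 on log2(value + 1). The 12921 loci with a mean of at least 1 over the 8 libraries entered. The parental and the knockout libraries each shared a mean over both Shld states, each of the 4 degron libraries had its own coefficient, and the spread came from the parental and knockout pairs (2 residual degrees of freedom, empirical Bayes moderation with a mean-variance trend). A lone degron library was thereby assumed to vary like those pairs. Another planned fit tested Shld itself in the 4 parental and knockout libraries with the line as a covariate (1 residual degree of freedom). P-values were adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and ± gives the standard error of the model.

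The second model, here the named-gene model, was chosen after the column names and the first calls were seen. It kept 8601 named genes with a mean of at least 5, left out small RNAs and unnamed loci, fitted each knockout library on its own and took the spread from the parental pair alone (1 residual degree of freedom, 23.6 prior degrees of freedom). Every other library was assumed to vary like that pair, although the knockout and mutant degron pairs were less even in fragments per unit. The restriction to 1 locus per symbol, the one with the highest mean, was added after secondary loci of genes had appeared among the calls, and left out 63 loci. Separate cultures are not stated for any pair, so p-values measure the spread between these libraries.

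Before the data were examined, the planned comparisons, the alternatives, the rule for named genes and 36 gene lists with 726 entries, of which 514 were measured, were fixed. By that rule the text draws on the 10 largest rises and 10 largest falls past the threshold in the 2 degron lines and in knockout against parental cells, 5 and 5 in other comparisons, SF3B1, and up to 4 members of each list with the largest differences. For the named-gene model up to 15 and 15 were listed, or 5 and 5 for differences between lines. Other genes are named as members of a list that passed the threshold, or as chosen after their values were seen. Some genes that passed are counted but are not reported here by name. For each list the median log2 difference was set against 10000 random lists of the same size matched on deciles of mean expression. Its percentile describes these libraries and is not a test of the conditions.

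Alternatives covered the pseudocount, the filter on low values, 2 other scalings, the moderation, a common Shld term, each parental or knockout library left out, and, added later, robust moderation, named genes only and a correction of each library for transcript length (lowess, span 0.3), for which 98.2% of the named genes had a length. Both models were tested on simulated data with 200 loci changed. For a log2 change of 1, the planned model recovered 0% of them in the wildtype degron comparison, 30.5% in the mutant degron comparison and 82% in knockout against parental cells. For a log2 change of 2 these shares were 97.5%, 99% and 99.5%. False calls among unchanged loci numbered 0, 13 and 11 at log2 1, and 8, 25 and 15 at log2 2, in the same order. Each value came from 1 simulated draw, and both degron comparisons had a median standard error of 0.19. The 0% and 30.5% thus do not measure a difference between those 2 lines. The named-gene model recovered 98.5% at log2 1 for the knockout pair. The simulated spread was the moderated one, so this does not test the prior of that model.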

Results

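Transcript levels were measured in 8 MEL202 libraries: parental cells, the knockout line, the mutant degron line and the wildtype degron line, each with and without Shld. SF3B1 is a core subunit of the SF3b complex of the U2 small nuclear ribonucleoprotein, which recognises the branch point of introns. Each state had 1 library, and the sum of rescaled values ran from 762679 in the wildtype degron line with Shld to 961994 in parental cells with Shld. Transcripts of RPL and RPS genes took 12.1% and 11.8% of that sum in the wildtype degron line and 16.6% to 21.0% in the other 6 libraries. Absolute depth was unknown.

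The target gene was examined first. SF3B1 stood at 266 and 240 rescaled FPKM in parental cells with and without Shld, at 158 and 138 in the knockout line, at 248 and 252 in the mutant degron line, and at 188 and 201 in the wildtype degron line. It fell by 0.77 ± 0.12 on the log2 scale in the knockout line against parental cells (limma, adjusted p = 0.021). With either parental or either knockout library left out, that adjusted p lay between 0.061 and 0.14, with the difference between -0.68 and -0.87, and without a level filter it was 0.071. Shld withdrawal left its RNA at +0.09 ± 0.17 in the wildtype degron line and +0.03 ± 0.17 in the mutant degron line, neither past the threshold; the degron acts on the protein, which was not measured here.

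The first comparison asked what withdrawal of wildtype SF3B1 does. In the wildtype degron line, HIST1H1C, a linker histone gene, fell by 1.31 ± 0.17 on the log2 scale (limma named-gene model, adjusted p = 0.00010), and ZNF358, GNG7, which encodes a G protein gamma subunit, and CPNE7 fell by 1.05, 0.92 and 0.92. GLI2, a transcription factor of hedgehog signalling, rose by 1.05 ± 0.19 (adjusted p = 0.018) and LINC00152, a long noncoding RNA, by 1.00 ± 0.20 (adjusted p = 0.032). Besides HIST1H1C, 0 members of any list passed over all genes tested. The 28 measured genes of G1/S and DNA replication all had values below 0, with a median of -0.19 at the 0th percentile of matched random lists, and the 29 of G2/M and mitosis had a median of -0.16, with 2 above 0. The 19 measured p53 targets had a median of +0.19 at the 100th percentile, with 14 above 0, and the 16 genes of the integrated stress response had a median of +0.24, with 15 above 0.

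The histone list, named for replication-dependent histones but also holding H1F0, had the lowest list median in this pair, -0.97 over 7 measured genes. Of the 4 that entered the named-gene model, 1 fell over all genes and 2 adjusted over the list alone. Part of this fall began from a raised level: with Shld this line had a median of +0.60 against the parental mean (percentile 99.9, 6 of 7 above 0, 2 higher adjusted over the list alone in the planned model), and HIST1H1C stood at 53.1 with and 20.8 without Shld, against 36.4 and 34.1 in parental cells. Genes of cholesterol synthesis had a median of -0.18 with 2 of 18 above 0, proteasome subunits +0.15 with 16 of 17 above 0, and heat shock genes +0.14 with 10 of 10 above 0. Percentiles for these 4 lists were 0, 0.01, 100.0 and 99.6. Also outside the middle 95% of random lists were immediate early genes (+0.19), MAPK output (+0.17), apoptosis regulators (+0.14) and ER chaperones (+0.11) above, and melanocyte lineage (-0.09) and transcripts mis-spliced in SF3B1-mutant cells (-0.07) below.

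In total 8 named genes passed, 3 higher and 5 lower, and 341 had an unadjusted p below 0.05. Besides the 6 above they were PCNA-AS1 (+4.82), an antisense RNA listed at 33.1 in the library without Shld and at 0.203 with it, and NSUN4 (-2.86), listed at 6.27 with Shld and 0.000129 without; both rest on an estimate near 0, and without strand PCNA-AS1 cannot be told from PCNA. With quantile or median scaling, which lowered the prior degrees of freedom from 23.6 to 12.4 and 11.9, 3 genes passed, namely HIST1H1C, NSUN4 and PCNA-AS1. The planned model passed 12 loci, 9 higher and 3 lower, of which 11 were small RNAs or unnamed, with MIR1250 (+5.03), SNORA10 (+4.69), SCARNA23 (+3.42), MIR4258 (-10.01) and LOC440354 (-3.87) as those with a name. Without a parental library 0 loci passed, and without either knockout library 2.

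Withdrawal of wildtype SF3B1 in cells without the mutant allele, if the column names of the knockout line hold, passed more genes than the 2 other withdrawals, 237 against 8 and 4. Genes of the p53 response rose, led by the cyclin-dependent kinase inhibitor CDKN1A (+1.73 ± 0.19, adjusted p = 1.4e-05, limma named-gene model) and the secreted stress factor GDF15 (+1.72 ± 0.29, adjusted p = 0.0011). Genes of DNA replication and mitosis fell, among them CENPA, the centromeric histone variant (-0.91), POLA1, a subunit of DNA polymerase alpha (-0.96), and TOP2A, a topoisomerase (-0.80). CDKN1A stood at 88.9 with Shld and 296 without it, against 98.9 and 109 in parental cells, and the knockout and parental libraries without Shld are both named as 4 days. The degron libraries without Shld are named as 2 days, so by these names the withdrawals compared here also differ in time.

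Of the 18 p53 targets in the model, 10 rose over all genes tested and 14 adjusted over the list alone, with 0 lower. They included ZMAT3 (+1.17), the antiproliferative gene BTG2 (+1.10), TP53INP1 (+1.01) and MDM2, the ubiquitin ligase of p53 (+0.84). The list median was +0.76 over 19 measured genes, all above 0, at the 100th percentile. The parental pair had a median of +0.05 at the 77th percentile. Of 28 genes of G1/S and DNA replication 7 fell over all genes and 24 adjusted over the list alone, with 0 higher, and a median of -0.53. POLE2 (-0.96), the helicase subunit MCM7 (-0.85) and RRM2, a ribonucleotide reductase subunit (-0.84), were among them. Of 29 genes of G2/M and mitosis 12 fell over all genes and 28 adjusted over the list alone, again with 0 higher, and a median of -0.62. Medians in the parental pair were +0.06 and -0.04 for these 2 lists.

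Among the other lists in the knockout pair, 2 of 15 genes of the integrated stress response rose, CHAC1, a glutathione-degrading enzyme (+1.39 ± 0.17), and SESN2 (+0.73), which is also in the p53 list (3 higher and 1 lower adjusted over the list alone). Of 8 genes of MAPK output 3 rose (4 higher and 1 lower adjusted over the list alone), CCND1 (+0.78), EPHA2 (+0.73) and DUSP4 (+0.66), and of 14 immediate early genes EGR3 rose (+1.30). HIST1H1C fell by 1.33 ± 0.17, from 27.6 to 10.4, and 3 of 4 histone genes fell adjusted over the list alone. LSS of cholesterol synthesis fell (-0.68), 1 of 17. HNRNPH1 fell (-0.85) among 23 SR proteins and splicing regulators, whose median was -0.20 with 2 above 0, against -0.13 at percentile 1.2 in the parental pair. BRD9, a chromatin gene with a known mis-spliced exon in SF3B1-mutant cells, fell (-0.61), 1 of 22 genes of that kind, with a median of -0.14, against -0.08 at percentile 2.3 in the parental pair. UQCRC2 of the respiratory chain fell (-1.18), 1 of 26 genes of oxidative phosphorylation, with a median of -0.13, against -0.18 in the parental pair. Heat shock (+0.22), inflammatory (+0.32), antigen presentation (+0.22), matrix (+0.16) and proteasome (+0.11) medians lay above the middle 95% of random lists, and ribosomal protein (-0.16) and small RNA host (-0.30) medians below it. In the parental pair these medians were +0.07, +0.15, +0.19, +0.27, +0.003, -0.28 and -0.25, in the same order. Matrix and ribosomal protein genes thus shifted further in parental cells, and antigen presentation and small RNA host genes almost as far.

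LOC390660 (-2.47) and PCNA-AS1 (+2.70) passed, each with an estimate at or near 0 in 1 library of the pair. Besides these, the largest falls outside the lists were those of CDKN2C (-1.21), MXD3 (-1.20), APOOL (-1.18), C18orf56 (-1.17), SPC24 of the kinetochore (-1.16), LOC100289092 (-1.13), IQGAP3 (-1.12) and FANCD2 of DNA crosslink repair (-1.07), and the largest rises those of RASD1 (+1.34), SEL1L3 (+1.33) and HIP1R (+1.13). In all 237 of 8601 genes passed, 84 higher and 153 lower, and 1127 had an unadjusted p below 0.05. This count depends on the scaling: 91 passed with quantile normalization and 79 with median scaling, all of them among the 237, and the simulated data did not test this.

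Of these 237 genes, 218 had the same sign in the wildtype degron line, where 68.2% of all 8601 had the same sign in both pairs, and 109 in the mutant degron line. The 84 that rose had a median of +0.78 in the knockout pair, +0.21 in the wildtype degron pair and -0.0050 in the mutant degron pair. For the 153 that fell the medians were -0.75, -0.28 and +0.01. Across the 8601 genes the changes in the knockout and wildtype degron pairs had a Pearson correlation of 0.51 (Spearman 0.50), those in the knockout and mutant degron pairs -0.06 (-0.12), those in the knockout and parental pairs 0.15 (0.16), and those in the wildtype degron and parental pairs 0.05 (0.03). Genes are not independent replicates, and these pairs share no library.

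**Figure D1:**
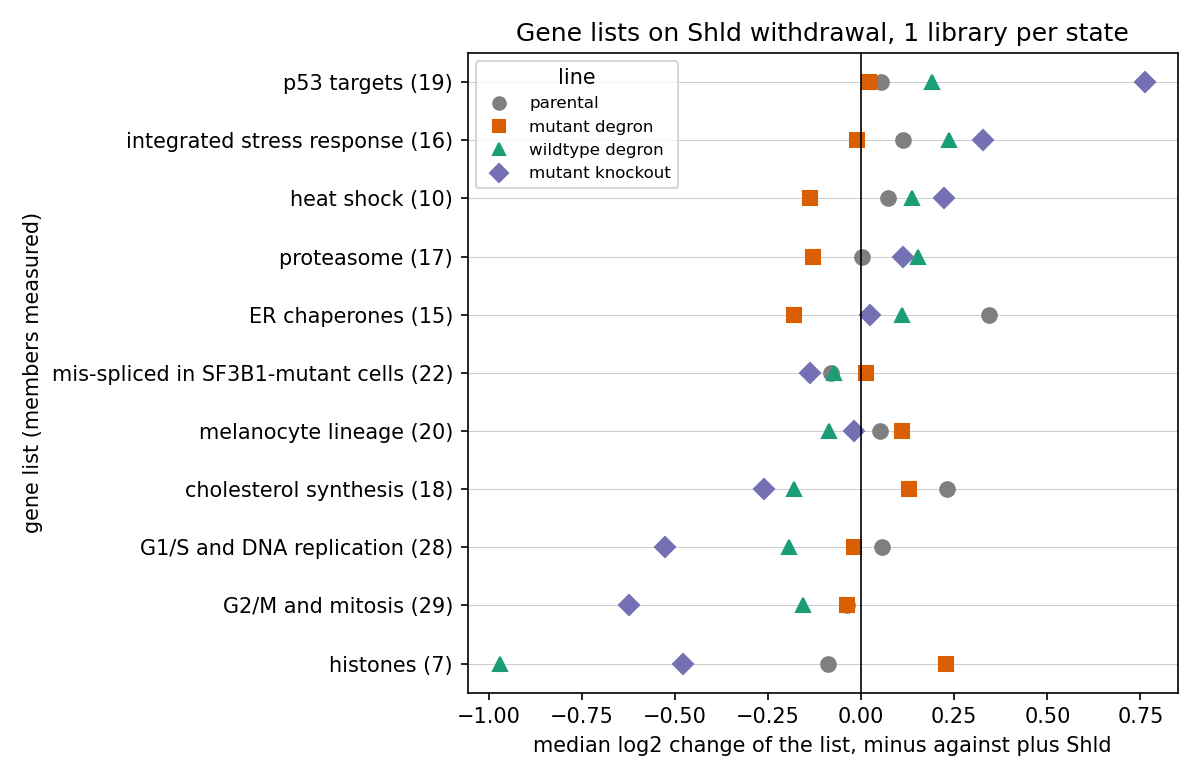
Median log2 change of 11 gene lists (number of measured members in parentheses) without against with Shld, 1 point per line, each from 1 library per state. The p53 list stood at 0.76 in the knockout line, 0.19 in the wildtype degron line, 0.05 in parental cells and 0.02 in the mutant degron line, and the sign of the last flipped to the other side of 0 under another scaling.

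The second comparison asked what withdrawal of mutant SF3B1 does. In the mutant degron line few genes moved past the threshold. LRFN1, a synaptic adhesion gene, rose by 1.88 ± 0.26 on the log2 scale, from 3.82 to 16.7, but stood at 5.23 and 10.9 in parental cells with and without Shld. HLA-C (+4.21), listed at 2.3e-05 with Shld and 17.5 without, was also near 0 in 1 parental library and shares sequence with other HLA genes. PCNA-AS1 (+3.20) and LOC390660 (-1.40) completed the 4 genes, 3 higher and 1 lower, with 146 at an unadjusted p below 0.05 (limma named-gene model). With quantile or median scaling 0 passed, and with the length correction LRFN1 passed.

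Among genes that did not pass, PHGDH, the first enzyme of serine synthesis, stood at 46.2 with and 88.5 without Shld (+0.92, adjusted p = 0.091). Of 22 genes known to be mis-spliced in SF3B1-mutant cells 0 passed over all genes and 2 rose and 1 fell adjusted over the list alone, with a median of +0.01 at the 77th percentile, or +0.06 at percentile 99.1 after the length correction, in a pair whose changes had a Spearman correlation of -0.23 with transcript length. In the wildtype degron pair their median was -0.07 at percentile 1.5, with 4 above 0 and 4 lower adjusted over the list alone, and the parental pair had -0.08 at percentile 2.3. The p53 median was +0.02, and the medians of G1/S and G2/M genes were -0.02 and -0.04. Lists at the upper end were cholesterol synthesis (+0.13, percentile 100.0), melanocyte lineage (+0.11, 19 of 20 above 0, percentile 99.9), histones (+0.23, percentile 99.8), the 3 measured fibroblast markers (+0.28, percentile 99.4) and ribosomal proteins (+0.06, percentile 97.8). The ribosomal protein median was +0.03 with quantile normalization, and +0.03 at percentile 95.7 after the length correction. At the lower end were ER chaperones (-0.18, 1 of 15 above 0), heat shock (-0.14, 1 of 10) and proteasome (-0.13, 0 of 17), each at the 0th percentile, followed by glycolysis and hypoxia (-0.11, 4 of 19, percentile 0.16) and SF3b and U2 genes (-0.07, 5 of 18, percentile 1.4).

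The planned model passed 36 loci, 16 higher and 20 lower, of which 34 were small RNAs or unnamed, with SNORD58C (+9.40), SNORA14A (+3.28), a secondary locus of MICB (+3.17), SNORD79 (-10.51), SNORD16 (-7.34), SNORD88C (-6.89), SNORA6 (-4.09) and LOC440354 (-2.86) as those with a name. Of these 36, 35 were listed at 0 in all 4 parental and knockout libraries. Without a parental library 0 passed, and relative to the mean change of parental and knockout pairs 0 passed.

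As a description of the 4 pairs, 118 loci differed at least 2-fold in the wildtype degron line, 138 in the mutant degron line, 186 in the knockout line and 143 in parental cells. Of these, 78, 97, 104 and 99 were small or unnamed. Among named genes with a mean of at least 5 the counts were 6, 5, 29 and 5.

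The third comparison tested whether the 2 degron lines responded differently. HIST1H1C differed by -1.79 ± 0.24 (wildtype degron change less mutant degron change, adjusted p = 0.00029, limma named-gene model) and PHGDH by -1.81 ± 0.27 (adjusted p = 0.0017), since PHGDH stood lower without wildtype SF3B1 (-0.89, from 139 with Shld) and higher without mutant SF3B1 (+0.92), though neither passed alone. With Shld, PHGDH already stood higher in the wildtype than in the mutant degron line, so these lines did not start level. GLI2 (+1.59) and the muscular dystrophy gene DMD (+1.60) differed in the direction opposite to HIST1H1C and PHGDH. Other genes past the threshold included HACL1 and MUT, 2 metabolic enzymes (-1.31 and -1.18), RECQL, a DNA helicase (-1.22), and SMARCA1, a chromatin remodeller (-1.10). The 22 genes known to be mis-spliced in SF3B1-mutant cells had a median difference of -0.10 at percentile 2.35, with 1 higher and 5 lower adjusted over the list alone.

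In all 21 genes passed, 4 higher and 17 lower, with 373 at an unadjusted p below 0.05. Only HIST1H1C, NSUN4 and PHGDH of them passed with quantile or median scaling, 0 higher and 3 lower. The changes of the 2 lines correlated at Pearson -0.21 and Spearman -0.29 across the 8601 named genes, and at -0.03 and -0.21 across all 12921 loci. The planned model passed 34 loci, 22 higher and 12 lower, all small or unnamed, and 0 without a parental library or 5 without a knockout library.

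Of the 8601 named genes, 34 stood at least 0.4 higher without mutant SF3B1 and at least 0.4 lower without wildtype SF3B1, a set chosen after the values were seen. In the knockout line against parental cells, which share no library with the degron pairs, this set had a median of +0.88, with 25 above 0. LMAN1, a cargo receptor of the secretory pathway (+2.07), RECQL (+1.79) and SMARCA1 (+1.54) were among them, and LINC00263 was below 0 (-1.11).

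**Figure D2:**
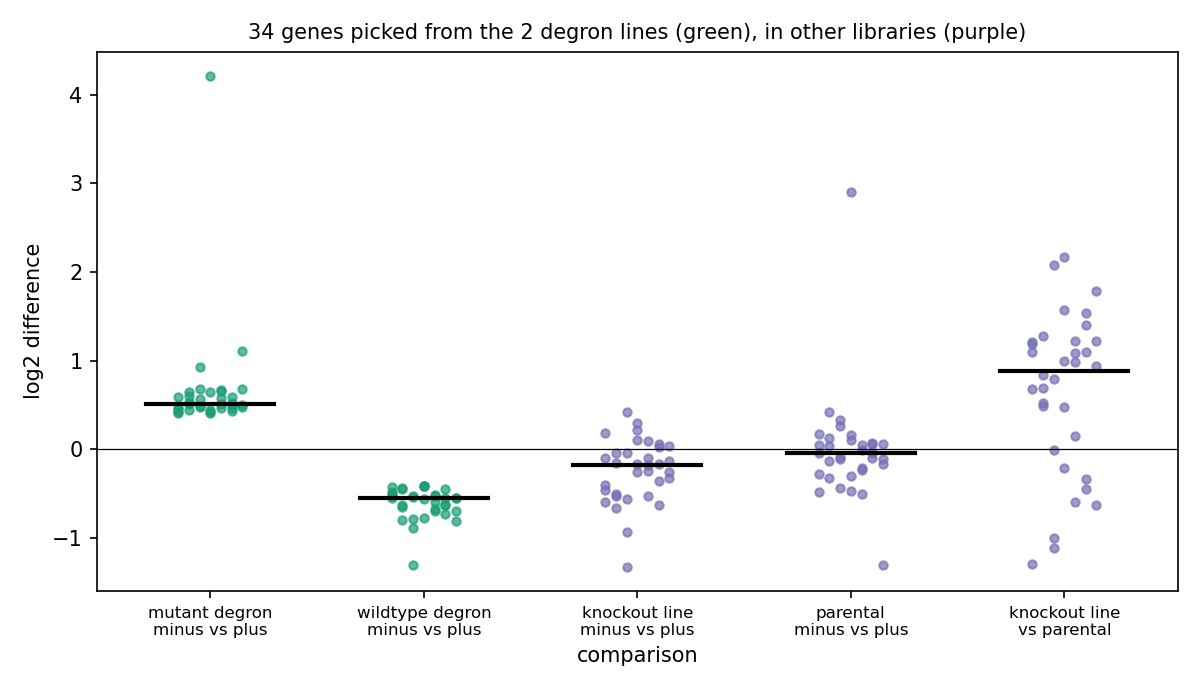
Log2 differences of these 34 genes, 1 point per gene with the median as a line, in the 2 degron pairs they were picked from (green) and in 3 comparisons of other libraries (purple). Medians were -0.17 in the knockout pair, -0.04 in the parental pair and +0.88 in the knockout line against parental cells.

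Set against the mutant degron line, the knockout line's change differed for 39 genes, 15 higher and 24 lower. CDKN1A differed by +1.69 ± 0.27 (adjusted p = 0.0034) and GDF15 by +1.78 ± 0.40 (adjusted p = 0.039). With quantile normalization 6 passed, 3 higher and 3 lower, and with median scaling 4, 3 higher and 1 lower; CDKN1A, CHAC1 and HIST1H1C were in both. Set against the wildtype degron line, NSUN4 (+2.78) and LOC390660 (-2.67) passed, with 269 at an unadjusted p below 0.05, and CDKN1A did not (+1.34 ± 0.27, adjusted p = 0.083).

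**Figure D3:**
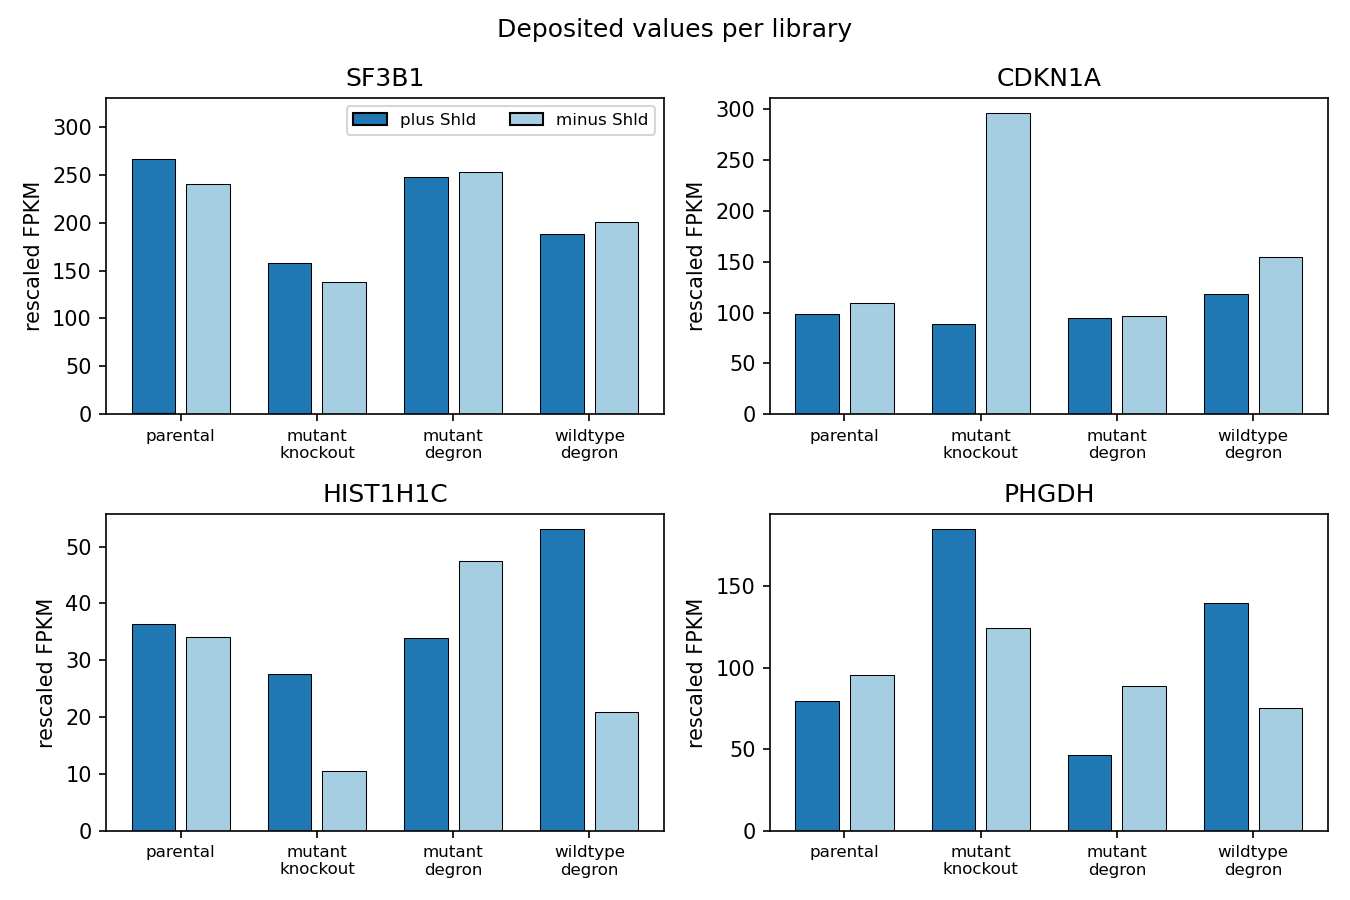
Rescaled FPKM of SF3B1, CDKN1A, HIST1H1C and PHGDH in each of the 8 libraries, with Shld in dark and without in light bars. CDKN1A stood at 296 in the knockout line without Shld and at 155 or lower in the other 7 libraries, and HIST1H1C at 10.4 in that library.

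The fourth comparison set the knockout line against parental cells, 2 libraries each with both Shld states together. Matrix, adhesion and TGF-beta response genes were higher in the knockout line and pigment cell genes lower. The adhesion gene NRCAM rose by 5.59 ± 0.12 on the log2 scale (limma, adjusted p = 0.0016), fibronectin FN1 by 4.80 ± 0.15 (adjusted p = 0.0020) and CTGF, a matricellular growth factor, by 4.34 ± 0.17 (adjusted p = 0.0024). HTN1, a salivary histatin, fell by 7.38 ± 0.18, as did the formin FMN2 (-5.11 ± 0.26), SPP1, or osteopontin (-4.91 ± 0.35), and MFAP2, a microfibril protein (-4.76 ± 0.09). Next came TTR (+3.94), NPR3 (+3.91), TGFBI (+3.81), SCRG1 (+3.68), SAMD11 (+3.60) and F2R (+3.51), and HTN3 (-4.71), SYNPR (-4.49) and AQP9 (-4.36).

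Of 15 TGF-beta response genes 10 rose and 1 fell, over all genes and adjusted over the list alone, with a median of +1.19. ID3 (+2.78), SMAD6 (+2.73) and ID1 (+1.90) encode inhibitors of differentiation and of SMAD signalling, and BHLHE40 fell (-0.82). Of 14 genes of extracellular matrix and adhesion 9 rose and 1 fell (11 and 1 adjusted over the list alone), with MMP2 (+2.29), COL5A1 (+1.79) and ITGA2 (+1.77) higher and POSTN lower (-2.77). Of 20 melanocyte lineage genes 11 fell (13 adjusted over the list alone), with a median of -1.02, including the pigment enzymes DCT (-2.32) and TYR (-1.41), OCA2 (-2.07) and RAB27A, which moves melanosomes (-2.05). Of 16 genes of uveal melanoma class and neural crest 7 rose (7 higher and 1 lower adjusted over the list alone), among them NGFR (+1.49), SATB1 (+1.35) and ID2 (+1.61), which is also in the TGF-beta list.

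Interferon response genes fell for 7 of 14 (7 adjusted over the list alone), with IFI6 (-2.34), ISG20 (-1.83) and OAS3 (-1.21), and the integrated stress response for 5 of 16 (2 higher and 7 lower adjusted over the list alone), with TRIB3 (-1.38), DDIT3 (-1.29) and SLC7A5 (-1.19). Of 22 genes known to be mis-spliced in SF3B1-mutant cells 5 rose and 2 fell, over all genes and adjusted over the list alone. They included TTI1 (+1.05), MAP3K7 (+0.91), DPH5 (+0.89), ARMC9 (+0.56), ABCC5 (-0.75) and CRNDE (-1.08), and the list median was -0.05, or +0.001 with quantile normalization. Of 18 SF3b and U2 genes SF3B3 rose (+0.82) while SF3B1 and SUGP1 (-0.56) fell. Of 19 p53 targets FAS (+0.56) and PLK2 (+0.91) rose, 5 adjusted over the list alone, with a median of +0.63, and 0 of the G1/S and G2/M genes passed. Both knockout libraries enter this +0.63, and the median change between them was +0.76, so part of it is the change on Shld withdrawal. The named-gene model set the knockout library with Shld alone against the parental mean, and there 10 of 28 G1/S genes and 5 of 29 G2/M genes were higher with 0 lower, and of 18 p53 targets 7 were higher and 2 lower.

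Markers of other cell types moved too. Of 4 measured neuronal and glial markers 3 rose, including MAP2 (+2.86) and TUBB3 (+0.52), and of 3 fibroblast markers LUM (-3.29) and POSTN fell and TAGLN rose (+0.93). Only 1 epithelial and 1 immune marker were measured; 0 passed over all genes and the epithelial 1 rose adjusted over the list alone, and 0 endothelial markers were measured.

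In all 2447 loci passed, 1113 higher and 1334 lower. The count was 0 without the parental library with Shld, 16 without the parental library without it, and 749 or 639 without a knockout library with or without Shld, and 1 derived line against its parent cannot separate the allele from the clone. Across all loci the change after mutant withdrawal and the knockout against parental difference, which share no library, had a Pearson correlation of -0.01 and a Spearman correlation of -0.06.

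The degron lines with Shld were also set against the parental mean. In the mutant degron line NRCAM (+4.03), CTGF (+3.06) and FN1 (+2.79) rose, and HTN3 (-3.98) and HTN1 (-3.36) fell. Of 15 TGF-beta response genes 5 rose (8 adjusted over the list alone), ID3 (+3.13), SMAD6 (+2.38), ID1 (+2.21), ID2 (+1.69) and SKIL (+1.22). OCA2 (-1.61) and RAB27A (-1.43) fell among 20 melanocyte genes, TRIB3 (-1.42) in the integrated stress response, and IFI6 (-1.93) among 14 interferon genes. TGF-beta response, matrix and melanocyte medians were +0.84, +0.92 and -0.42 here, +1.19, +1.25 and -1.02 in the knockout line, and +0.20, +0.53 and +0.17 in the wildtype degron line. Differences in the knockout line's directions thus also arose in a line whose mutant allele was not knocked out. This rests on 1 library with Shld. In the wildtype degron line SYNPR, a synaptic vesicle gene, fell by 4.54 ± 0.14 (limma, adjusted p = 0.0081), as did MYD88, an adaptor of innate immune receptors (-2.69). Ribosomal proteins had a median of -0.77 with 0 of 20 above 0, of which 16 fell adjusted over the list alone (median -0.29 with quantile normalization), and oxidative phosphorylation a median of -0.53, with 18 of 26 lower and 1 higher adjusted over the list alone (median -0.41 with that normalization).

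The planned model passed 272 loci in the mutant degron line (149 higher, 123 lower) and 10 in the wildtype degron line (3 higher, 7 lower), with 2931 and 4000 at an unadjusted p below 0.05. The named-gene model passed 1776 and 3110. In the planned model, 0 or 1 passed in either line without a parental library, and 47 and 1 without a knockout library.

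Shld itself was tested in the parental and knockout pairs together. In the planned fit 0 of 12921 loci passed, with 641 at an unadjusted p below 0.05 and a lowest adjusted p of 0.34 (limma). By its column names the knockout pair is also a withdrawal of wildtype SF3B1. Its changes would then enter the spread of this fit, so 0 calls do not show that Shld has no effect. In the parental pair alone, ER chaperones had a median of +0.34 (14 of 15 above 0), matrix and adhesion genes +0.27 (13 of 14), cholesterol synthesis +0.23 (13 of 18) and ribosomal proteins -0.28 (2 of 20), values with no test. With quantile normalization the last was -0.04.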

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

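Among the tests below, the length tests and the test on the 5 genes of the reverse direction were set before their results were seen; the bound of the latter was loosened afterwards, and all other tests were chosen after the result was seen. Each gene named here is one whose change differed between 2 lines in a test of the difference itself, and list medians are named where they had opposite signs in the 2 degron lines and lay outside the middle 95% of the random lists in both, below it in 1 line and above it in the other, a difference that was not tested.

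In the named-gene model, the change after withdrawal of wildtype SF3B1 less that after withdrawal of mutant SF3B1 was negative for HLA-C (-4.98), NSUN4 (-2.84), PHGDH (-1.81), HIST1H1C (-1.79), HYI (-1.31), HACL1 (-1.31), WDR34 (-1.28), LINC00263 (-1.27), CPNE7 (-1.26), KIAA0196 (-1.23), RECQL (-1.22), MGC16025 (-1.21), MUT (-1.18), SMARCA1 (-1.10), RTF1 (-1.10) and RDX (-1.08). It was positive for LOC390660 (+1.60), DMD (+1.60), GLI2 (+1.59) and RFTN1 (+1.28). HLA-C, NSUN4 and LOC390660 have an estimate at or near 0 in at least 1 of the 8 libraries.

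Genes that stood at least 0.4 higher without mutant SF3B1 and at least 0.4 lower without wildtype SF3B1 numbered 34 of 8601, against 2.01 if the 2 changes were independent. The reverse direction had 5 genes against 0.26, so the excess was not particular to 1 direction. The 2 changes correlated at Pearson -0.21 across these 8601 genes, so they were not independent. In 4 other libraries the 34 genes had a median knockout against parental difference of +0.88, with 25 of 34 above 0. The middle 95% of matched random lists lay between -0.17 and +0.14. Those lists were matched on mean expression and not on variability, and genes picked for large changes may have a wider range. The value thus speaks against chance selection from noise as the whole account without excluding it. The median was +1.01 over 30 genes after the length correction, so length bias, as far as this correction removes it, does not account for that difference. In the parental pair some of the 34 genes passed 0.4 in either direction, among them HLA-C (+2.90) and PUF60 (-1.31). The median of the 34 genes there was -0.041, with 14 above 0. Shld was withdrawn from both degron lines and the genes were picked for opposite changes in them, so this value adds little about Shld itself. Activity of the mutant protein, which lowers transcripts it mis-splices, may account for part of these genes, but the 5 genes of the reverse direction had a median of -0.22, inside their random range of -0.48 to +0.46, where the prediction had asked for a value below it; with 5 genes that range is too wide to decide, which is why the bound was loosened. Picked at 0.3 instead of 0.4, 12 reverse genes had a median of +0.23 at percentile 95.6 (random range -0.28 to +0.27), or +0.14 over 13 genes after the length correction, on the other side of 0 from the predicted fall. The reverse genes gave no support to this account. They are not among the 34, and mis-splicing that lowers transcripts predicts nothing for genes that fell without mutant SF3B1. They thus cannot decide it, which leaves it open. The +0.88 of the 34 genes has the direction this account calls for, but a difference between clones could also give it. Against this account alone, the 34 genes had a median of -0.17 at percentile 0.02 when wildtype SF3B1 was withdrawn from the knockout line (as its column names have it), and a difference between clones stays open.

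Against the mutant degron line, the knockout line's change was higher for GDF15 (+1.78), CDKN1A (+1.69), DSP (+1.54), SEL1L3 (+1.52) and CHAC1 (+1.45) and lower for HLA-C (-3.99), LRFN1 (-2.25), HIST1H1C (-1.80), C18orf56 (-1.56) and PHGDH (-1.49). Against the wildtype degron line, NSUN4 (+2.78) and LOC390660 (-2.67) differed. By the column names both comparisons set 4 days without Shld in the knockout line against 2 days in the degron line.

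Higher p53 targets and lower cell cycle genes after withdrawal of wildtype SF3B1 were the second pattern. Shld or 4 days without it had a p53 median of +0.054 in the parental pair, against +0.76 in the knockout line, and after the length correction the latter was +0.77, so neither is the whole account. Loss of wildtype SF3B1 protein is a candidate explanation, since the median lay at the 100th percentile in both lines that, by the column names, carry a degron on wildtype SF3B1 and was +0.021 at the 78th percentile in the mutant degron line. By those names both degron lines were at 2 days without Shld and the knockout line at 4 days, so only the degron lines compare at equal time. The median in the knockout line exceeded that in the wildtype degron line by 0.57. Longer withdrawal, the absence of the mutant allele and a difference between clones cannot be told apart for that excess, because each line has 1 time.

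Small RNAs were the third pattern. Over all loci, the difference between the degron lines was +10.51 for SNORD79, +7.34 for SNORD16, +6.89 for SNORD88C, +6.43 for SNORA6 and +5.03 for MIR1250, and -10.01 for MIR4258 and -9.40 for SNORD58C. Of 47 loci that passed in any of the 3 degron comparisons, 89.4% were listed at 0 in all 4 parental and knockout libraries, against 0.34% of the 12921 tested. A locus at 0 there reached the level filter only through the degron libraries. Those 4 libraries set the spread, so its own spread before moderation was 0. That may be the source of most of these calls, and the high share was largely fixed in advance by the model. No biological explanation was tested.

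The list medians that met this rule, wildtype degron pair first, were -0.97 and +0.23 for the histone list, +0.11 and -0.18 for ER chaperones and unfolded protein response, +0.14 and -0.14 for heat shock, -0.18 and +0.13 for cholesterol synthesis, -0.087 and +0.11 for melanocyte lineage and +0.15 and -0.13 for proteasome. In the parental pair they were -0.09, +0.34, +0.07, +0.23, +0.05 and +0.003, in the same order. ER chaperones and cholesterol synthesis thus had larger medians in size there than in either degron pair. With Shld, medians against parental cells, wildtype degron line first, were +0.60 and -0.05 for histones and +0.19 and -0.15 for cholesterol synthesis. They were +0.17 and -0.42 for melanocyte lineage and -0.27 and +0.11 for proteasome. In these lists each line's change ran opposite to its starting difference. For ER chaperones and heat shock this held only in the mutant degron line. Each library with Shld enters both values, so noise in it could give such opposite changes.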

How the results depend on the processing

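Robust moderation, the named-gene settings and every alternative to the named-gene model were chosen after the data were seen; the cause of a move was not tested unless given. Over 102 gene and comparison pairs named here, 0 of 1076 values reversed, 801 kept their side of the threshold and 275 lost it. Changes of the median locus under the scalings were at most 0.0443. Shld itself gave 0 loci under all 7 alternatives, which share the limit that the knockout pair may carry a degron. The planned correlations across all loci stayed between -0.023 and +0.0034 for mutant withdrawal with knockout against parental, and between -0.056 and -0.0039 for the 2 degron lines.

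Planned counts moved as follows. For the wildtype degron line (12 loci) they were 21 with pseudocount 0.1, 113 without a level filter, 1 with a common Shld term, 0 relative to the parental and knockout pairs, 20 with robust moderation, 2 with named genes, and 0 to 2 with a library left out. For the mutant degron line (36) they were 253 without a filter, 15 at a mean of at least 5, 2 with a common term, 0 relative, 0 with named genes, 4 in the named-gene model and 0 to 33 with a library left out. For the difference of the 2 (34) they were 307, 20, 0 with a common term, 0 with named genes, 21 in the named-gene model and 0 to 5. Knockout against parental (2447) gave 776 without a filter and 0 to 749 with a library left out, where fewer libraries set the spread. The mutant degron line with Shld (272) gave 25 with a common term, 621 with robust moderation, 819 with named genes, 1776 in the named-gene model and 0 to 47. The wildtype degron line with Shld (10) gave 21 with pseudocount 0.1, 6 with pseudocount 5, 92 without a filter, 16 at a mean of at least 5, 20 with median scaling (5 higher, 15 lower), 2 with a common term, 46 with robust moderation, 1504 with named genes, 3110 in the named-gene model and 0 to 1.

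Counts at 2-fold with pseudocount 0.1, pseudocount 5, no filter and a mean of at least 5 were 276, 38, 230 and 35 in the wildtype degron line, 233, 67, 288 and 41 in the mutant degron line, 258, 53, 355 and 34 in parental cells and 413, 67, 373 and 66 in the knockout line.

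In the named-gene model, the knockout pair (237) gave 57 at a mean of at least 1, 91 with quantile normalization, 79 with median scaling and 113 without a trend. The difference of the degron lines (21) gave 5, 3, 3 and 5, and that of the knockout and mutant degron lines (39) gave 14, 6, 4 and 14, and 80 at a mean of at least 10. With the length correction 204 of 215, 16 of 17 and 29 of 29 were shared with the 237, 21 and 39. The scalings lowered the prior degrees of freedom from 23.6 to 12.4 and 11.9, with 1 residual degree of freedom, and depth is unknown, so none of these counts is firm.

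In the 4 pairs with and without Shld, signs of list medians that flipped under a scaling were those of p53 targets, SR proteins and small RNA hosts in the mutant degron line, core spliceosome and NMD factors in the wildtype degron line, immediate early genes and fibroblast markers in parental cells, and melanocyte markers in the knockout pair, all close to 0. The immune marker value in the knockout pair went from -0.05 to 0 with quantile normalization. In the comparisons with parental cells signs flipped for mis-spliced transcripts, ribosomal proteins (-0.17 to +0.06 with quantile normalization) and proteasome in the knockout line, SR proteins and MYC targets in the mutant degron line with Shld, and mis-spliced transcripts and immune and neuronal markers in the wildtype degron line with Shld. Ribosomal protein medians also moved under quantile normalization from -0.28 to -0.04 in the parental pair and from -0.16 to -0.06 in the knockout pair. No analysis paired by replicate was possible because each group has 1 library; the fit of Shld itself pairs the parental and the knockout libraries by line.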

Other observations

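All values here were examined only as list results, with no further tests. In the knockout line against parental cells, genes of MYC targets and ribosome biogenesis had a median of +0.32 at the 100.0th percentile, with 2 of 17 higher and 1 lower over all genes (7 and 1 adjusted over the list alone). NOP58, a nucleolar protein (+0.68), and MYC (+0.52) rose and ODC1, an enzyme of polyamine synthesis, fell (-0.94). NMD factors had a median of +0.16, with UPF3B (+0.93) and SMG8 (+0.50) higher among 12 (1 adjusted over the list alone). Of 32 core spliceosome genes AQR (+0.87), PRPF8 (+0.48) and EFTUD2 (+0.44) rose, and 0 adjusted over the list alone. The 15 iron and heme genes had a median of -0.13, and FTH1, the ferritin heavy chain, fell (-0.74). Of 19 glycolysis and hypoxia genes ALDOC (-1.21), PFKFB4 (-0.90) and PFKP (-0.60) fell, 5 adjusted over the list alone. Cholesterol synthesis had 1 of 18 higher, SQLE (+1.34), and 3 lower, STARD4 (-1.07), INSIG1 (-0.85) and MVD (-0.82). Of 16 apoptosis regulators BMF (+1.00) and BID (+0.84) rose and BIK (-1.17) and BAD (-0.75) fell. NLRC5, an activator of MHC class I genes, fell (-1.17), 1 of 9 antigen presentation genes. Of 5 inflammatory genes and of 4 small RNA host genes 0 passed, with medians of +0.14 and -0.28. Mitochondrially encoded genes had 0 of 13 measured.

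ER chaperones, matrix and immediate early genes were also set side by side across the lines with Shld. The 15 ER chaperones had medians of +0.69 in the mutant degron line and +0.40 in the wildtype degron line against parental cells, with 7 higher in the former and 5 higher and 2 lower in the latter adjusted over the list alone; over all genes 0 passed in the planned model, and in the named-gene model 8 were higher in the former and 7 higher and 2 lower in the latter. Matrix and adhesion genes had medians of +0.92 and +0.53, with 14 and 12 of 14 above 0. All 29 genes of G2/M and mitosis were above 0 in the mutant degron line with Shld, with a median of +0.51 at the 100th percentile, and 0 passed in the planned model while 17 did in the named-gene model. CTGF (+3.06) passed in the mutant degron line, 1 of 18 immediate early genes.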
